A study of Mnemiopsis leidyi with 24 samples.

How the data were processed

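The series holds 24 RNA libraries of Mnemiopsis leidyi, a ctenophore (comb jelly), in 8 groups of 3. One set of 12 libraries is labelled as nascent RNA of epithelium with comb rows, the other as total RNA of epithelium. Each set has a control group and 3 groups of regenerating tissue, taken after 30 minutes, after 1 hour and after 2 hours. Tissue, injury and kind of RNA differ together between the sets, so no comparison can say which of them matters. Groups were taken from the sample labels. The labels give each library a letter and no replicate number, so replicates were numbered in accession order and the numbers pair nothing. No batch or date is labelled.

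The authors deposited a separate table for each set, both in RPKM, reads scaled by gene length and library size, which are normalized values and not counts. Per the labels' protocols, RNA was extracted with a QIAGEN RNeasy kit and libraries were made with a NEB Next Ultra kit. Per the submitters' processing notes the software was Partek, named there without a version or settings. The aligner, genome build and annotation are not given in the sources used here, nor is the way nascent RNA was isolated. The tables were normalized separately, so levels were compared only within a table. Every gene listed reached 1.00 RPKM in at least 1 library. There are 9101 genes in the nascent and 8120 in the total RNA values, with 7633 in both.

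Some values lie above 0 but under 0.001 RPKM (548 in the nascent table, 260 in the total table), far below what 1 read is worth. Values under 0.001 were therefore treated as listed at 0 when single genes were described. The numbers of genes at 0 per library count only values of exactly 0. Of 55 ribosomal protein genes, which every cell uses, at most 1 was listed under 0.001 RPKM in any library. Depth was estimated from the spacing of low values and each gene's coding length, since 1 read sets the smallest step. With values of up to 50 reads, 64.5 to 79.6% of nascent and 66.7 to 75.2% of total values came out whole within 0.05 reads. This gave 6.23 to 10.3 M (mega) reads per nascent library and 2.70 to 13.4 M per total library, with 1.15 to 2.20 M and 0.591 to 2.73 M of them in listed genes. For a gene of median coding length (1023 and 1011 nucleotides) 1 read was worth 0.0952 to 0.157 RPKM in nascent and 0.0740 to 0.366 RPKM in total libraries. The estimate was tested on simulated data. The values were not whole often enough for a count test.

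The files pair gene IDs with the best protein hit in other databases, and a hit with an E-value up to 1.00e-04 and a usable description gave the gene its name (58.7% of nascent and 61.3% of total genes). The only p-value-like column deposited by the authors is the E-value of that hit per the file headers, made by a search whose settings are not given in the sources used here. These names are similarities, not proven orthologs. A table of 19625 annotated genes of a later assembly matched 0 of the IDs and was not used, so no coordinates are given. Proteins of the files were compared with blastp 2.17.0 (E-value limit 1e-10, 9588 proteins), and 235 genes with a copy of at least 95% identity over at least 90% of the shorter protein are marked as uncertain, since the authors' counting could have split their reads.

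Values were taken as log2(RPKM + 1). Genes with a mean of at least 1 RPKM over the 12 libraries of a table were tested (6988 nascent, 6586 total). Each table was fitted with limma 3.58.1 in R 4.3.3 (tables read with version 1.17.8 of its data-table package), with 1 coefficient per group, a trend of spread on mean expression and 8 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were each time against control, 2 hours against 30 minutes, and a moderated F test of any time. A term for the difference between tables was tested in a joint fit of all 24 libraries for the genes tested in both (5785). Overlaps of calls between times share control libraries, so they stand beside the overlap of independent lists (n1 × n2 / N) and 100 simulations of unchanged groups against the same controls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

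The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule names genes that pass the threshold, have a name, and have all 3 regenerating libraries on one side of the 3 controls. It takes the 12 largest rises and 12 largest falls at the time with most calls in a table and 6 of each at the other times, and adds called members of the lists as counts with examples. Where fewer than 4 genes passed, the 6 of smallest p are given without a verb of change. The 23 lists join genes by words in their names: immediate early and bZIP factors, other transcription factors, heat shock proteins and chaperones, Wnt signalling, TGF-beta and BMP signalling, apoptosis, the MAP kinase pathway, extracellular matrix and its proteases, actin cytoskeleton, DNA repair, cell cycle and replication, histones, ribosomal proteins, RNA polymerase and splicing, ubiquitin and proteasome, oxidative stress and iron, ion channels and calcium signalling, and mitochondrial respiration. Markers of other cell types the tissue could hold were comb plate and cilia, muscle, photoproteins and opsins, digestive enzymes, and neuronal and secretory genes. Lists of at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

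On simulated data with 200 changed genes in 10 runs, the nascent fit at 1 hour (6988 genes) recovered 0, 2.54 and 10.6% of 2-, 4- and 8-fold changes, with 6.45% of calls false. The total fit at 1 hour (6586 genes) recovered 10.3, 59.6 and 77.6%, with 6.40% false. The difference between tables at 1 hour (5785 genes) recovered 0.299, 4.18 and 18.3%, with 11.7% of calls false, above the nominal 5%.

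Alternatives planned at the outset were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 RPKM, libraries rescaled to equal medians of ratios, quantile normalization, no trend, limma array weights, a fit of only the 2 groups compared, leaving out each library in turn, rank correlation, and the estimated correlation and rescaling for lists. Added after seeing the data were a mean of at least 20 RPKM, leaving out the 2 libraries of each table with most genes at 0, a separate spread in each table for the difference, 14 lists without members whose name shows another function, lists after quantile normalization or without each library, Gene Ontology terms of 10 to 200 tested members taken from the files, and the marking of near copies.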

Results

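RNA of the ctenophore Mnemiopsis leidyi was profiled in control tissue and in tissue that had been regenerating for 30 minutes, for 1 hour or for 2 hours. The stated purpose was to compare control with regenerating tissue in both total and nascent RNA. Total RNA came from injured epithelium and nascent RNA, newly made transcripts, from injured epithelium with comb rows, with 3 libraries in each of 4 groups per table. Fold changes are on the log2(RPKM + 1) scale and understate the change of genes with low values. The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries, which may be technical.

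Depth and detection moved with the groups. In total RNA the control libraries had an estimated depth of 5.78, 2.70 and 7.87 M (mega) reads, against 8.96 to 13.4 M in the regenerating libraries. They listed 1206, 2008 and 522 of 8120 genes at 0, against 181 to 389 in the others. Nascent control libraries listed 4670, 3554 and 3054 of 9101 genes at 0, those of 1 hour 1501, 1140 and 825, and replicate 3 of 2 hours 3970. Their estimated depth was 7.16 to 9.39 M reads in controls and 6.23 to 8.13 M at 1 hour. Replicates of a group correlated across genes at r of 0.654 to 0.873 in nascent RNA and 0.751 to 0.979 in total RNA. The first principal component held 45.8% of the variance in total RNA and set the 3 controls (75.9 to 88.7) apart from the other libraries (-40.4 to -4.95). In nascent RNA it held 32.2%, and replicate 3 of 30 minutes (39.7) and of 2 hours (57.0) lay on the side of the controls (57.4 to 116), away from the other regenerating libraries (-75.7 to -31.0).

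**Figure D1:**
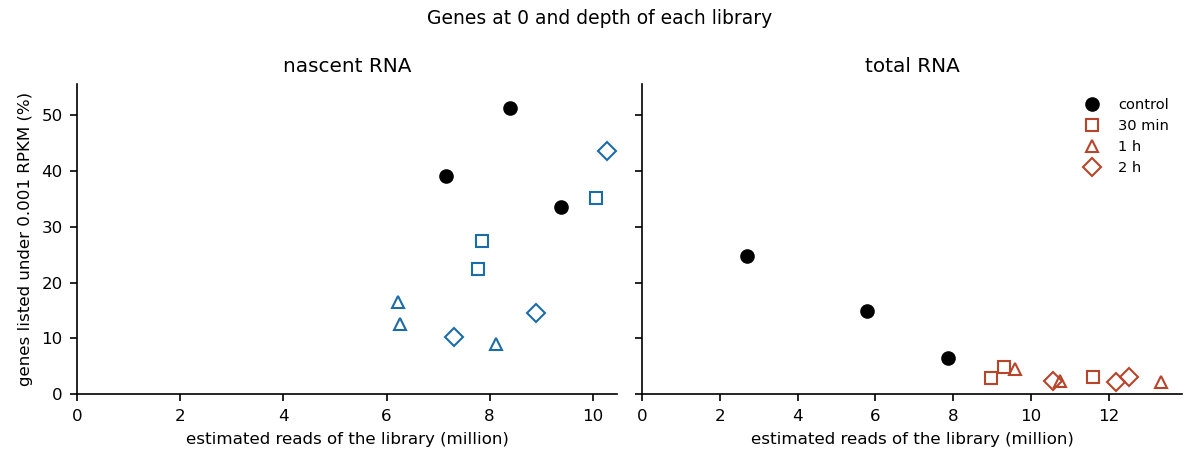
Percent of listed genes at exactly 0 RPKM in each library (y axis, labelled there as under 0.001 RPKM) against the estimated depth in M reads (x axis), 1 point per library with a shape for each group and controls filled in black, for nascent RNA (blue) and total RNA (red). The total RNA controls reach 24.7% of genes at 0 and the nascent controls 51.3%.

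In total RNA at 1 hour, single genes for secreted peptides, calmodulin and cytoplasmic actin were among those that rose most, and single genes named after a basement membrane protein and a splicing factor among those that fell most. A secretory peptide-37 gene (ML200246a) rose from 2.15 ± 1.12 to 575 ± 249 RPKM (SD, n = 3), a log2 change of 7.48 ± 0.551 (SE, limma adjusted p = 1.98e-05). A second secretory peptide-37 gene (ML184414a) rose by 5.94, and neuronal pentraxin-2 (ML24994a), a secreted lectin-like protein, from 1.58 ± 0.476 to 264 ± 63.7 RPKM. Cytoplasmic actin (ML322211a) rose from 84.1 ± 46.6 to 1805 ± 173 RPKM, a log2 change of 4.60 ± 0.622 (SE, limma adjusted p = 3.05e-04). Calmodulin (ML258256a), the calcium sensor, was at 2.23, 0 and 0.891 RPKM in controls and at 85.3, 68.0 and 40.7 RPKM at 1 hour (log2 change 5.10). Other large rises were those of a hemocyanin hit (ML09108a, 7.22), galactosylceramide sulfotransferase (ML238318a, 5.24), growth arrest-specific protein 2 (ML258234a, 4.74) and, with a near copy, obscurin (ML19853a, 4.69). Another secretory peptide-37 gene (ML039715a) went from 0.439, 2.82 and 0 RPKM to 68.1, 57.1 and 52.3 RPKM (5.08), and a PIF1-like hit (ML24921a), with a near copy, from 0 in all controls to 29.7, 40.1 and 25.2 RPKM. A flagellar attachment zone hit (ML03225a) rose by 5.68 ± 1.46 (limma adjusted p = 0.0103) and a tetranectin-like gene (ML056964a) fell by -4.69 ± 1.21 (0.0105). Neither passed without control replicates 1 and 2, which leaves 1 control library that is assumed to vary like the other groups (0.101 and 0.0636). A laminin-like epi-1 gene (ML120750a), named after a basement membrane protein, fell from 27.9 ± 13.1 to 0.233 ± 0.0878 RPKM, a log2 change of -4.44 ± 0.329 (SE, limma adjusted p = 1.98e-05). Charged multivesicular body protein 1b (ML124217a), of the membrane-scission machinery, fell from 40.2 ± 7.73 to 2.55 ± 0.221 RPKM. Falls of -3.65 to -2.93 were those of nucleoredoxin 1 (ML104336a), multidrug resistance protein 1A (ML06974a), an isochorismatase hit (ML009115a), splicing factor SRSF12 (ML31014a), mitochondrial ribosomal protein L18 (ML05739a) and H/ACA subunit 1 (ML02548a), which serves RNA modification. An S30-ubiquitin hit (ML01824a) fell by -3.36 and, with a near copy, acidic protein P2 (ML053619a) by -3.28 (limma adjusted p = 0.00436), which did not pass with array weights (0.0569). The 60S acidic protein P1 hit (ML02404a) was at 777, 93.0 and 394 RPKM in controls and listed near 0 in all 3 libraries of 1 hour.

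In total RNA at 1 hour, of 18 immediate early and bZIP factors 8 rose and 0 fell (adjusted over the list alone 8 and 1), among them v-Fos (ML182032a, 4.36 ± 0.682), an ATF-6 hit (ML031714a, 3.76 ± 0.417) and AP-1 (ML1541120a, 3.14 ± 0.678). AP-1's call at 1 hour ended with a pseudocount of 5 (limma adjusted p = 0.0539). Of 47 other transcription factors 12 rose and 2 fell (11 and 1 alone), and Sox1 (ML047927a) went from 3.75 ± 2.03 to 85.6 ± 22.7 RPKM (SD, n = 3). Of 22 genes of the MAP kinase pathway, which relays stress and growth signals, 14 rose and 0 fell (14 and 0 adjusted over the list alone). They included MAPKAP kinase 2 (ML310320a, 3.12), a MAP kinase kinase (ML02994a, 3.05) and dual specificity phosphatase 7 (ML051316a, 2.78), which acts on MAP kinases. Of 43 matrix genes 11 rose and 3 fell (the same alone), with matrix metalloproteinase-24 (ML14875a) up by 3.72 and integrin beta-6 (ML00901a) up by 3.48. Over all 6586 genes tested 1774 rose and 726 fell. The rises among the other transcription factors and the matrix genes were thus near the share over all genes. Of 44 actin cytoskeleton genes 18 rose and 5 fell (18 and 6 alone), with gelsolin-like protein 1 (ML01137a, 3.81) and vinculin (ML148910a, 2.89), which ties integrins to actin. Of 33 heat shock genes 3 rose and 5 fell (3 and 4 alone), among them heat shock cognate 4 (ML18558a), which fell from 453 ± 97.6 to 123 ± 63.6 RPKM.

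Limma called 2500 of 6586 genes at 1 hour, 1774 up and 726 down. Rescaling to equal medians of ratios gave 1660 up and 1072 down (60.8% up against 71.0%), and quantile normalization 1187 up and 1231 down (49.1%). The median change of all genes was 0.26 as deposited, 0.11 and -0.07.

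In total RNA at 30 minutes v-Fos and secreted proteins led the rises. V-Fos (ML182032a), a partner of AP-1 in early gene control, rose from 6.95 ± 1.84 to 1101 ± 579 RPKM (SD, n = 3), a log2 change of 7.02 ± 0.682 (SE, limma adjusted p = 1.23e-04), and AP-1 (ML1541120a) rose by 4.79 ± 0.678. A secreted protein hit (ML19406a) rose by 7.52, secretory peptide-37 genes by 6.91 (ML200246a) and 6.44 (ML02012a), peptide-29 (ML11975a) by 6.75, and a rhodopsin hit (ML14767a) by 7.02. Multivesicular body protein 1b (ML124217a) fell from 40.2 ± 7.73 RPKM to a mean of 0.782 RPKM (log2 change -4.55, limma adjusted p = 7.68e-06), epi-1 (ML120750a) by -4.50 and the isochorismatase hit (ML009115a) by -3.75. Matrix metalloproteinase-24 (ML14875a, 3.55), vinculin (ML148910a, 2.64), talin-1 (ML015610a, 2.48), Sox1 (ML047927a, 2.89) and phosphatase 7 (ML051316a, 2.49) also rose. Glutathione S-transferase 2 (ML01926a), a detoxifying enzyme, fell by -2.93. Photoproteins 2 and 6 (ML085730b and ML085734b), the light emitters of this animal, stood at 601, 4.15, 303 and 107, 1.19, 73.8 RPKM in controls and under 2.1 RPKM at 30 minutes. Both passed (limma adjusted p = 0.0213 and 0.0356), have near copies and varied widely between control libraries. Photoprotein 2 did not pass without 30 minutes 1 (0.0689) or 2 (0.0627) or control 1 (0.0786) or 3 (0.0520), and photoprotein 6 without any 30 minutes replicate or control 1 or 3 (0.0748 to 0.123) or with a pseudocount of 5 (0.0523). Neither passed with only these 2 groups in the fit (0.0557 and 0.0661). An elastin-like gene (ML069131a) was named by the rule from values that count as 0 in control 2 and in all 3 libraries of 30 minutes, so its groups were not apart. Limma called 1303 genes up and 691 down (65.3% up), against 1477 and 927 (61.4%) with equal medians of ratios and 964 and 1044 (48.0%) after quantile normalization. The median changes were 0.15, 0.14 and -0.08, and the count fell from 1994 to 582 with only these groups in the fit and to 1240 without 30 minutes replicate 2. Without control replicates 1 and 2, which leaves 1 control library that is assumed to vary like the other groups, it was 1215, 599 up and 616 down.

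In total RNA at 2 hours secretory peptide-37 (ML02012a) rose from 0.697 ± 0.916 to 238 ± 30.2 RPKM (SD, n = 3), a log2 change of 7.26 ± 1.16 (SE, limma adjusted p = 8.08e-04). The rhodopsin hit (ML14767a, 6.88), the secreted protein hit (ML19406a, 7.23), secretory peptides 37 (ML200246a, 6.62) and 29 (ML11975a, 6.33) and the hemocyanin hit (ML09108a, 6.38) also rose. V-Fos (ML182032a) was at 106 ± 64.6 RPKM, a rise of 3.55 ± 0.682. Dishevelled (ML017418a, 1.86) and a frizzled receptor (ML003224a, 1.84), both of Wnt signalling, rose, as did talin-1 (ML015610a, 3.18), vinculin (ML148910a, 3.33) and the replication helicase subunit mcm2 (ML10001a, 3.11). A tetranectin-like gene (ML056964a) fell from 172 ± 61.1 to 2.19 ± 0.871 RPKM, a log2 change of -5.73 ± 1.21 (SE, limma adjusted p = 0.00362). Epi-1 (ML120750a) fell by -4.64, the isochorismatase hit (ML009115a) by -4.19 and multivesicular body protein 1b (ML124217a) by -3.83. Ribosomal protein S20 (ML03311a) passed at -4.84 (limma adjusted p = 0.0324), and not without control replicate 1 (0.0789) or 2 (0.0811), with a pseudocount of 0.1 (0.0529), after quantile normalization (0.0570) or with only these 2 groups in the fit (0.111). Photoprotein 2 (ML085730b), with a near copy, passed at -5.27 from controls of 601, 4.15 and 303 RPKM, and not without control 1 (0.0810) or 3 (0.0546) or 2 hours 1 (0.0618) or 2 (0.0665), or with only these 2 groups in the fit (0.0513). Limma called 1865 genes up and 620 down (75.1% up), against 1644 and 1052 (61.0%) with equal medians of ratios and 1182 and 1181 after quantile normalization, with median changes of 0.34, 0.12 and -0.06. Any time differed from control in 2220 genes.

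**Figure D2:**
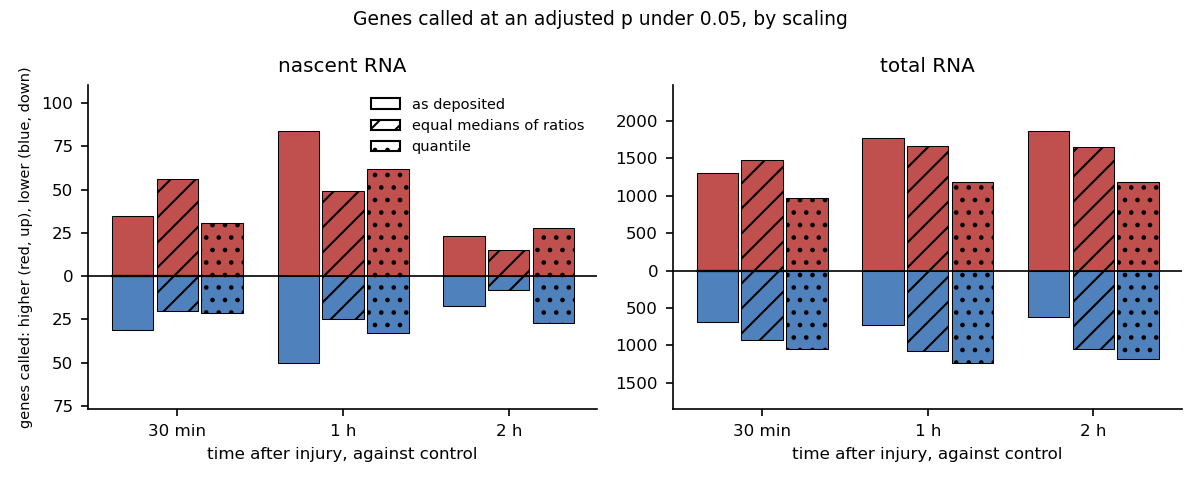
Genes past an adjusted p of 0.05 in limma (y axis, number of genes) for the 3 times against control (x axis), rises in red and falls in blue, for the values as deposited, equal medians of ratios and quantile normalization. In total RNA at 1 hour the rises number 1774, 1660 and 1187 and the falls 726, 1072 and 1231.

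Ribosomal and respiratory genes lay below other genes as groups in total RNA at each time, which is what camera tests. Of 93 ribosomal genes 3 rose and 36 fell at 30 minutes, 6 and 49 at 1 hour, and 6 and 37 at 2 hours (4 and 44, 8 and 49, 6 and 38 adjusted over the list alone). Their camera adjusted p was 1.23e-09, 1.50e-11 and 3.79e-10 (adjusted p = 0.982, 0.906 and 0.836 with an estimated correlation). Ribosomal protein L30 (ML29622a) fell from 3256 ± 1654 to 713 ± 80.1 RPKM at 2 hours, and mitochondrial ribosomal protein S16 (ML015712a) from 47.1 ± 3.88 to 10.8 ± 1.51 RPKM. L30 did not pass without control replicates 1 and 2, which leaves 1 control library that is assumed to vary like the other groups (limma adjusted p = 0.0618). Of 34 mitochondrial respiration genes 19, 15 and 16 fell and 2 rose at each time (21, 22 and 17 falls and 2 rises alone). Their camera adjusted p was 8.27e-07, 8.49e-07 and 8.44e-07 (adjusted p = 0.982, 0.906 and 0.836 with an estimated correlation). A complex I subunit (ML05003a) fell from 171 ± 26.0 to 37.1 ± 1.89 RPKM at 1 hour. The MAP kinase list lay above other genes, with 12, 14 and 14 of 22 genes up and 1, 0 and 1 down (13 and 3, 14 and 0, 14 and 1 alone) and a camera adjusted p of 0.0253, 0.0194 and 0.0147 (adjusted p = 0.982, 0.906 and 0.836 with an estimated correlation). This call ended at 30 minutes without control replicate 1 (0.0569) or 3 (0.0709) or 30 minutes replicate 1 (0.0543), and after quantile normalization (0.0577). At 1 hour it ended without control replicate 1 (0.0555) or 3 (0.0588). Of 45 oxidative stress genes 4 rose and 10 fell at 30 minutes (the same alone; camera adjusted p = 0.0291, and adjusted p = 0.982 with an estimated correlation). That call, for a position below other genes, ended without control replicate 3 (0.145), 30 minutes replicates 1 (0.0543) or 2 (0.0773), and after quantile normalization (0.132). Of 28 photoprotein and opsin genes 4 rose and 5 fell at 2 hours (2 and 0 alone; camera adjusted p = 0.0269 for a position below other genes, and adjusted p = 0.837 with an estimated correlation), and 13 of them have near copies. It ended without control replicate 1 (0.105) or 3 (0.0740), without 2 hours replicate 3 (0.0691), and with equal medians of ratios (0.121). No list call in total RNA turned direction under either scaling. After quantile normalization the camera adjusted p in time order was 0.00356, 0.00170 and 0.0248 for the ribosomal list. It was 2.37e-04, 2.73e-04 and 3.70e-04 for the respiratory list.

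The other lists did not pass in total RNA against control, though single members did. In time order the genes up and down were 9 and 3, 11 and 3, 15 and 2 of 43 matrix genes (the same alone) and 11 and 3, 18 and 5, 17 and 2 of 44 actin cytoskeleton genes (12 and 4, 18 and 6, 17 and 3 alone). They were 10 and 3, 12 and 2, 14 and 2 of 47 other transcription factors (9 and 3, 11 and 1, 17 and 2 alone), and 7, 8 and 7 up with 0 down of 18 immediate early factors (7 and 0, 8 and 1, 8 and 1 alone). Ion channel and calcium genes gave 11 and 3, 22 and 3, 22 and 4 of 67 (9 and 2, 22 and 3, 22 and 4 alone), with metabotropic glutamate receptor 5 (ML30555a) up by 2.25 at 1 hour. Among markers of other cell types, comb plate and cilia genes gave 8 and 5, 7 and 4, 7 and 4 of 57 (8 and 4, 5 and 1, 6 and 3 alone). Neuronal and secretory genes gave 13 and 9, 12 and 8, 11 and 11 of 43 (14 and 13, 12 and 8, 11 and 11 alone), digestive enzymes 12 and 3, 17 and 2, 17 and 1 of 61 (12 and 3, 15 and 2, 16 and 1 alone), with carboxypeptidase D (ML02201a) up by 3.45 at 1 hour. Muscle genes gave 2 and 1, 4 and 1, 3 and 1 of 8 (2 and 1, 4 and 1, 4 and 1 alone), with a striated myosin heavy chain (ML02275a) up from 3.19 ± 0.429 to 56.3 ± 5.56 RPKM at 1 hour. Photoproteins and opsins gave 3 and 2 at 30 minutes and 3 and 0 at 1 hour (3 and 1, 1 and 0 alone), and oxidative stress genes 5 and 9 at 1 hour and 6 and 3 at 2 hours (4 and 7, 4 and 1 alone). The ubiquitin and proteasome list gave 19 and 20, 30 and 20, 32 and 15 of 113 (22 and 24, 31 and 20, 33 and 17 alone), with the ligase RNF213 (ML200238a) up by 3.15 at 1 hour. RNA polymerase and splicing genes gave 9 and 10, 11 and 11, 11 and 7 of 58 (12 and 10, 11 and 11, 11 and 6 alone). Heat shock genes gave 2 and 2, 3 and 5, 3 and 0 of 33 (1 and 1, 3 and 4, 2 and 0 alone), cell cycle genes 4 and 3, 6 and 2, 4 and 2 of 33 (3 and 3, 6 and 2, 4 and 1 alone), and DNA repair genes 3 and 2, 6 and 2, 5 and 2 of 22 (3 and 2, 6 and 3, 4 and 2 alone). TGF-beta genes gave 2 and 1, 2 and 1, 4 and 1 of 9 and apoptosis genes 2 and 3, 2 and 2, 3 and 1 of 7 (the same alone). Wnt genes gave 1 and 0, 1 and 1, 3 and 0 of 5 (the same alone), and histones 0 and 0, 1 and 0, 2 and 0 of 6 (0 and 0, 1 and 0, 1 and 0 alone), where at 30 minutes 1 histone had an unadjusted p under 0.05 in limma.

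Between 2 hours and 30 minutes limma called 0 genes in total RNA, with 456 at an unadjusted p under 0.05 where chance gives 329. With equal medians of ratios or quantile normalization it also called 0. The 6 genes of smallest p all had a limma adjusted p of 0.246, among them matrix metalloproteinase-14 (ML42444a) with a log2 difference of 2.63. The others were a degenerin-like gene (ML145837a, log2 difference 1.79) and 4 genes without a name (ML327411a 2.56, ML003232a -3.79, ML00737a 1.66 and ML30693a 1.49). Without 30 minutes replicate 3 limma called 1 gene, Homer protein homolog 2 (ML06361a, -2.89 ± 0.325, adjusted p = 0.0237), named after its values were seen. As groups, 5 Wnt genes (camera adjusted p = 0.00366) and 43 matrix genes (0.0208) lay above other genes in the change from 30 minutes to 2 hours, and 57 comb plate and cilia genes (0.00383) and 43 neuronal and secretory genes (0.0208) below them, with median differences of 1.06, 0.49, -0.08 and 0.00 against 0.22 for all genes. With an estimated correlation none passed (adjusted p = 0.108, 0.108, 0.891 and 0.822). No member of these lists passed alone over all genes. The matrix call ended without 2 hours replicate 1 (0.134) or 30 minutes replicates 2 (0.135) or 3 (0.241), the cilia call without 2 hours replicate 2 (0.0525) or 30 minutes replicates 1 (0.162) or 3 (0.0962), and the neuronal call without 2 hours replicate 3 (0.0749) or 30 minutes replicate 3 (0.203).

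In nascent RNA at 30 minutes, v-Fos (ML182032a) rose from 168 ± 137 to 2595 ± 160 RPKM (SD, n = 3), a log2 change of 4.27 ± 0.570 (SE, limma adjusted p = 0.00280). A secretory peptide-37 gene (ML039715a) rose by 5.31 ± 0.675 (limma adjusted p = 0.00195). The AHNAK hit (ML218819a), a large scaffold protein in other animals, was at 5.40, 2.36 and 213 RPKM in controls and rose to 1885 ± 978 RPKM, a log2 change of 6.70 ± 1.14 (SE, limma adjusted p = 0.0153). AP-1 (ML1541120a) was at 0, 0 and 1.38 RPKM in controls and 250, 225 and 6.24 RPKM at 30 minutes (limma adjusted p = 0.0374). A second secretory peptide-37 gene (ML085023a) rose by 5.73, a mitochondrial pif1 helicase hit (ML00052a) by 6.15 and matrix metalloproteinase-24 (ML14875a) by 4.04. A PIF1-like hit with a near copy (ML24921a) was listed at 0 in all controls and at 182, 556 and 102 RPKM at 30 minutes. Carbohydrate sulfotransferase 11 (ML047945a) fell by -5.35, and prolyl 4-hydroxylase alpha-1 (ML257632a), which modifies collagen, from 35.9, 24.1 and 14.3 to 0.726, 0 and 0 RPKM. Signal cointegrator 1 subunit 1 (ML293113a, -4.31) and sodium bicarbonate transporter-like protein 11 (ML218834a, -4.09) also fell, and mitochondrial GTPase 1 (ML07975a) went from 150, 21.6 and 52.0 RPKM to 0 in each library. Also down was ribonucleoprotein H (ML076910a, -4.15).

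The calls of v-Fos and ML039715a at 30 minutes held without each library in turn. Those of ML24921a and ML257632a ended without control replicate 1 (limma adjusted p = 0.0533 and 0.0580), ML085023a without 30 minutes replicate 1 (0.0814) or 2 (0.0754), and AHNAK without 30 minutes replicate 2 (0.0572) or control replicates 1 (0.0714) or 2 (0.0537). ML00052a and ML047945a ended without the same 3 libraries (0.0557 to 0.0797), ML293113a without those or control replicate 3 (0.0557 to 0.0754), and ML218834a without 30 minutes 2, control 1 or 2, or 1 hour 2 or 3 (0.0517 to 0.0988). ML14875a ended without 30 minutes replicates 1 or 2, control replicate 1 or any 1 hour replicate (0.0538 to 0.131). ML07975a ended without 30 minutes replicates 1 or 2, any control or 1 hour replicate 2 (0.0517 to 0.108). AP-1 ended without those, 1 hour replicate 3 or 2 hours replicate 2 (0.0501 to 0.140), and ML076910a without 30 minutes replicates 1 or 2, any control or any 1 hour replicate (0.0537 to 0.117). Limma called 66 of 6988 genes at 30 minutes, 35 up and 31 down, with 1215 at an unadjusted p under 0.05. Equal medians of ratios gave 56 up and 20 down (73.7% up against 53.0%), and quantile normalization 31 and 21, with median changes of 0.18, 0.44 and -0.09. Without a library the count was 10 (control replicate 1), 23 (control 2), 25, 26 and 348 (30 minutes 1, 2 and 3), 34 and 33 (1 hour 2 and 3) and 156 (2 hours 3). With a pseudocount of 5 it was 27 up and 42 down. With only these groups in the fit limma called 0 (856 at an unadjusted p under 0.05).

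In nascent RNA at 1 hour, the AHNAK hit, the RNA helicase DHX16 and the chromatin proteins MLL3 and ATRX were among the genes that rose most, and a tektin-1 and a beta-tubulin gene were among those that fell. AHNAK (ML218819a) rose to 2207 ± 523 RPKM, a log2 change of 7.02 ± 1.14 (SE, limma adjusted p = 0.0104), and secretory peptide-37 (ML039715a) to 142 ± 33.3 RPKM (log2 change 5.72, limma adjusted p = 7.89e-04). The RNA helicase DHX16 hit (ML14777a) rose from 0.488 ± 0.133 to 257 ± 114 RPKM, the histone methyltransferase MLL3 (ML015714a) from 0.905 ± 1.14 to 62.5 ± 8.71 RPKM. The chromatin remodeller ATRX (ML069124a) was at 0, 22.5 and 0 RPKM in controls and 149, 183 and 187 RPKM at 1 hour, and Rac1 (ML274423a), a switch of cell motility, at 0, 0 and 6.66 against 76.9, 59.0 and 77.9 RPKM. The corepressor CIR1 (ML03296a, 6.65), AP-1 (ML1541120a, 5.86), sorbin (ML10213a, 5.47), a GRIP-domain hit (ML04766a, 5.28), pif1 (ML00052a, 5.27), with a near copy the PIF1-like hit (ML24921a, 6.43, controls at 0), matrix metalloproteinase-24 (ML14875a, 4.40), Sox2 (ML234028a, 2.65) and v-Fos (ML182032a, 2.51) rose as well. Tektin-1 (ML047948a), a filament protein of cilia, fell from 113 ± 41.2 to 5.09 ± 2.66 RPKM, a log2 change of -4.27 ± 0.785 (SE, limma adjusted p = 0.0222). Beta-tubulin (ML24281a) fell from 419 ± 116 to 44.8 ± 20.1 RPKM, and a flagellar calcium-binding hit (ML00881a) from 1023 ± 255 to 118 ± 83.6 RPKM. Sulfotransferase 11 (ML047945a, -4.60), LAP2 (ML019227a, -3.96), ankyrin-2 (ML13779a, -3.82), transporter-like 11 (ML218834a, -3.79), ATP synthase d (ML07463a, -3.63), PARP12 (ML21529a, -3.47), neurotrypsin (ML10613a, -3.15), outer dense fiber protein 3 (ML03453a, -3.12) and ectin (ML183515a) also fell.

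Among genes named at 1 hour in nascent RNA, the call of ML039715a held without each library. That of AHNAK ended without 1 hour replicate 1 (limma adjusted p = 0.0752) or control 1 (0.0695), and metalloproteinase-24 without any 1 hour replicate (0.115, 0.0784 and 0.0867). MLL3, Rac1, tektin-1, Sox2 and ML218834a ended without any 1 hour replicate or control 1 or 2 (0.0597 to 0.184), and ATRX without any 1 hour replicate or control 1 or 3 (0.0535 to 0.0969). CIR1, AP-1, sorbin, ML04766a, ML047945a, LAP2, beta-tubulin, outer dense fiber protein 3 and ectin ended without any 1 hour or control replicate (0.0510 to 0.191). Pif1 and the PIF1-like hit ended without any of these but 1 hour replicate 2 (0.0508 to 0.148). V-Fos ended without any 1 hour replicate, control 1 or 3 or 30 minutes 1 (0.0540 to 0.190). DHX16, ATP synthase d and ML00881a ended without any 1 hour or control replicate or 30 minutes 1 (0.0509 to 0.206), ankyrin-2 also without 2 hours 1 (0.0538 to 0.218), and PARP12 and neurotrypsin also without 30 minutes 2 (0.0524 to 0.235). Limma called 84 genes up and 50 down, with 1499 at an unadjusted p under 0.05. Equal medians of ratios gave 49 up and 25 down and quantile normalization 62 and 33, with median changes of 0.61, 0.66 and -0.07. Without a library the count was 13, 13 and 17 (1 hour 1, 2 and 3), 15, 39 and 68 (control 1, 2 and 3), 203 and 333 (2 hours 2 and 3) and 84 and 293 (30 minutes 1 and 3). With a pseudocount of 5 it was 53 up and 66 down, with array weights 750, without trend 47, with only these groups 568, and 87 without control 1 and 2 hours 3.

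In nascent RNA at 2 hours, serine/threonine-protein kinase 3 (ML141214a) went from 0, 0 and 0.291 RPKM in controls to 62.9, 45.2 and 73.2 RPKM, a log2 change of 5.79 ± 0.617 (SE, limma adjusted p = 4.00e-04). Transcription factor tau subunit sfc7 (ML128437a), of RNA polymerase III initiation in yeast, went from 0.389, 0 and 0 to 36.4, 72.8 and 94.0 RPKM. Secretory peptide-37 (ML039715a) rose to 198 ± 66.2 RPKM, a log2 change of 6.17 ± 0.675 (SE, limma adjusted p = 4.00e-04). These 3 calls held without each library. AHNAK (ML218819a, 6.58), CIR1 (ML03296a, 6.09) and GAS2-like protein 2 (ML012025a, 4.72) also rose. Transporter-like 11 (ML218834a) was at 28.7, 29.5 and 17.1 RPKM in controls and listed at 0 at 2 hours. NADP-specific glutamate dehydrogenase (ML17724a, -3.55), beta-tubulin (ML24281a, -3.26), a tektin-1 gene (ML305512a, -2.70), L30 (ML29622a, -1.90) and, with a near copy, tubulin beta-4B (ML07214a, -3.57) fell. V-Fos (ML182032a) did not pass at 2 hours (log2 change 0.97, limma adjusted p = 0.454). The call of GAS2-like protein 2 ended without 2 hours 1 (0.0743) or 2 (0.0594), ML218834a without those or control 1 (0.0549 to 0.0790), AHNAK without those or control 1 or 2 (0.0707 to 0.102), and CIR1 without those or any control or 1 hour replicate (0.0680 to 0.159). The 5 falls other than ML218834a ended without any control, any 1 hour replicate or 2 hours 2 (0.0526 to 0.138). They ended also, for ML07214a, without 2 hours 3 (0.0601) or 30 minutes 1 (0.0616), for ML24281a and ML305512a without 2 hours 1 or 30 minutes 1 (0.0537 to 0.151), and for ML17724a without 2 hours 1 (0.151). Limma called 40 genes, 23 up and 17 down, with 960 at an unadjusted p under 0.05. Equal medians of ratios gave 15 and 8 and quantile normalization 28 and 27, with median changes of 0.46, 0.46 and -0.02. Without a library it was 15 and 26 (control 1 and 2), 20, 21 and 22 (1 hour 1, 2 and 3), 11, 11 and 105 (2 hours 1, 2 and 3) and 87 (30 minutes 3), with only these groups 1, and with a pseudocount of 5 it was 21 up and 41 down. Any time differed from control in 33 genes, and in 6 and 12 without control 1 and 2, 20, 20 and 21 without 1 hour 1, 2 and 3, 18, 52 and 127 without 2 hours 1, 2 and 3, and 133 without 30 minutes 3.

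**Figure D3:**
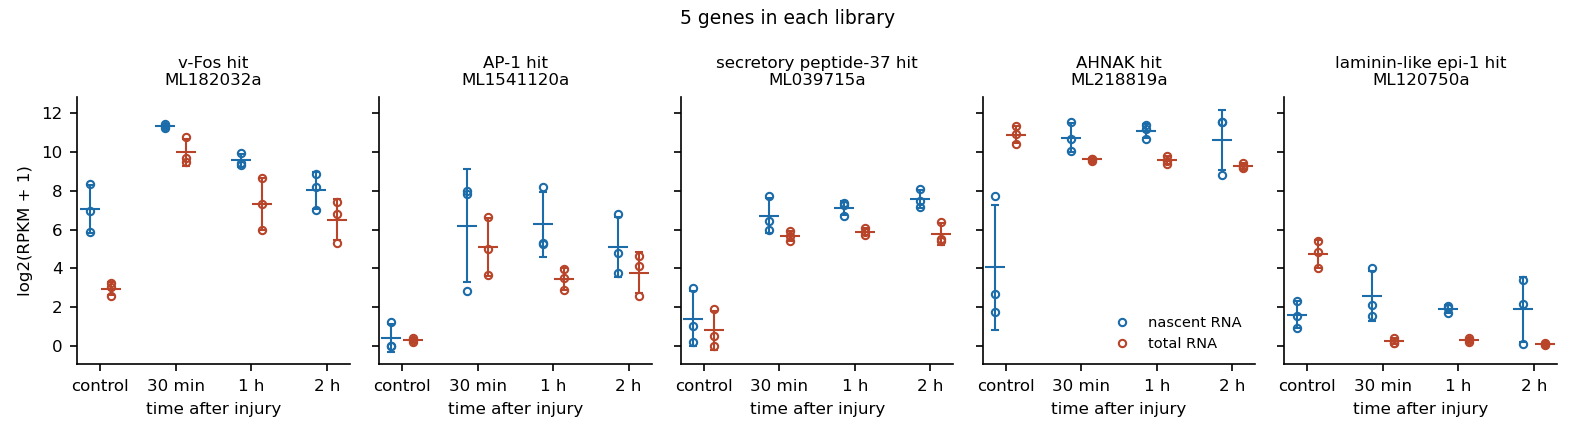
Log2(RPKM + 1) (y axis) in control, 30 minutes, 1 hour and 2 hours (x axis) for v-Fos, AP-1, a secretory peptide-37 gene, AHNAK and laminin-like epi-1, with 1 point per library, a dash for the mean and a bar for the SD (n = 3), nascent RNA in blue and total RNA in red. V-Fos reaches 2595 RPKM in nascent and 1101 RPKM in total RNA at 30 minutes, and AHNAK moves in opposite directions in the tables.

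Ribosomal, respiratory, ciliary and oxidative stress genes lay below other genes as groups in nascent RNA at each time, though limma called none of their members at 30 minutes. The median change of the cilia list at 1 hour was -0.10, against 0.61 for all genes. Of 91 ribosomal genes limma called 0, 6 and 1 down in time order (0, 45 and 10 adjusted over the list alone; 8, 54 and 29 at an unadjusted p under 0.05). Their camera adjusted p was 1.53e-05, 9.50e-21 and 5.30e-13 (adjusted p = 0.664, 0.276 and 0.512 with an estimated correlation). The examples S20 (ML03311a, -2.21), L29 (ML012410a, -2.18), L22 (ML221324a, -1.95) and S3a (ML006118a, -1.92) fell at 1 hour, and each of these calls ended without any 1 hour or control replicate (limma adjusted p = 0.0550 to 0.200). Those of L29, L22 and S3a ended also without 30 minutes 1 (0.0633, 0.0516 and 0.0516), and L29 without 30 minutes 2 (0.0557) or 2 hours 1 (0.0552). After quantile normalization the ribosomal list did not pass at 30 minutes (0.0844). Of 34 respiratory genes 0, 1 and 0 were down (0, 5 and 0 alone; 8, 14 and 9 at an unadjusted p under 0.05), with camera adjusted p = 1.57e-04, 8.83e-09 and 4.54e-06 (adjusted p = 0.324, 0.109 and 0.328 with an estimated correlation). Of 63 comb plate and cilia genes, a marker list of another cell type in the comb rows, 0, 5 and 3 were down (5, 9 and 7 alone; 17, 17 and 12 at an unadjusted p under 0.05). Their camera adjusted p was 0.00336, 4.12e-05 and 3.51e-04 (adjusted p = 0.664, 0.351 and 0.512 with an estimated correlation), and at 2 hours 0.0635 without 2 hours replicate 2. Of 44 oxidative stress genes 0, 2 and 0 were down and 0 up (3 down, 1 up and 3 down, 1 up and 4 down alone; 12, 14 and 10 at an unadjusted p under 0.05), with camera adjusted p = 0.00357, 2.81e-04 and 0.00900 (adjusted p = 0.324, 0.109 and 0.342 with an estimated correlation). At 2 hours this was 0.0635 without 2 hours replicate 2, 0.0536 without control replicate 2 and 0.0894 after quantile normalization. Glutathione S-transferases fell at 1 hour (ML343422a -2.76, ML01927a -2.50), the first not without any 1 hour replicate or control 1 or 2 (0.0784 to 0.105), the second not without any 1 hour or control replicate, 30 minutes 1 or 2 hours 1 (0.0539 to 0.195). The direction of these lists held under both scalings, but quantile normalization weakened the ribosomal calls. At 1 hour the ribosomal median went from -1.45 to -0.49, and that of all genes from 0.61 to -0.07. The camera adjusted p of the ribosomal list was then 9.00e-04 at 1 hour and 0.00138 at 2 hours.

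The other lists did not pass in nascent RNA against control at any time (camera), and limma called few members over all genes. Called in time order were 2, 2 and 0 up of 18 immediate early factors (3 up and 2 down, 5 and 2, 2 and 0 alone; 5, 8 and 3 at an unadjusted p under 0.05). Of 66 other transcription factors 0, 2 and 0 were called (1 up, 1 up and 1 down, 0 alone; 6, 14 and 5), Sox2 up and PRD44 (ML001922a, -2.09) down at 1 hour, the latter not without any 1 hour replicate or control 1 or 2 (0.0784 to 0.148). Of 36 heat shock genes 1, 1 and 0 were down (1 up and 2 down, 1 and 1, 0 alone; 9, 7 and 5), a DnaJ hit (ML090124a) by -2.87 and -2.57, not kept at 30 minutes without any control, 30 minutes 1 or 2, 1 hour 2 or 3 or 2 hours 1 or 2 (0.0517 to 0.0948), nor at 1 hour without any control or 1 hour replicate, 30 minutes 1 or 2 or 2 hours 1 (0.0524 to 0.233). Of 47 matrix genes 1, 1 and 0 were up (1, 1 and 1 alone; 8, 10 and 4), of 40 neuronal and secretory genes 1 up, 1 up and 1 down, and 1 up (2 up, 1 and 1, 2 and 1 alone; 6, 7 and 6), and of 22 DNA repair genes 1 up and 1 down, the same at 1 hour, and 0 (1 and 1, 1 and 1, 0 and 1 alone; 4, 5 and 4). Of 10 TGF-beta genes 1 was down at 30 minutes, Smad nuclear-interacting protein 1 (ML068130a, -2.75; not without any control, 30 minutes 1 or 2 or 1 hour 2 or 3, 0.0517 to 0.0946), and 0 later (1, 0 and 0 alone; 1, 1 and 2). Of 28 photoproteins and opsins 1 was up at 1 hour, a Gq-coupled rhodopsin hit (ML03263a, 3.36; not without any 1 hour replicate or control 1 or 3, 0.0536 to 0.148), and 0 at other times (0, 1 up and 2 down, 1 up alone; 2, 7 and 3). Of 55 RNA polymerase and splicing genes 1 was up and of 47 digestive enzymes 1 down, both at 1 hour and at no other time (the same alone; 7, 6 and 6, and 4, 7 and 2). Limma called 0 members at each time of the 19 MAP kinase genes (1, 4 and 3 at an unadjusted p under 0.05), 120 ubiquitin genes (11, 24 and 8), 34 cell cycle genes (4, 4 and 1), 56 ion channel genes (6, 6 and 4), 47 actin genes (6, 10 and 6), 7 apoptosis genes (2, 3 and 1), 6 Wnt genes (0, 0 and 0) and 6 histones (0, 0 and 0), and 0 alone as well. It called 0 of 8 muscle genes at each time (0, 2 up and 0 alone; 3, 2 and 2).

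**Figure D4:**
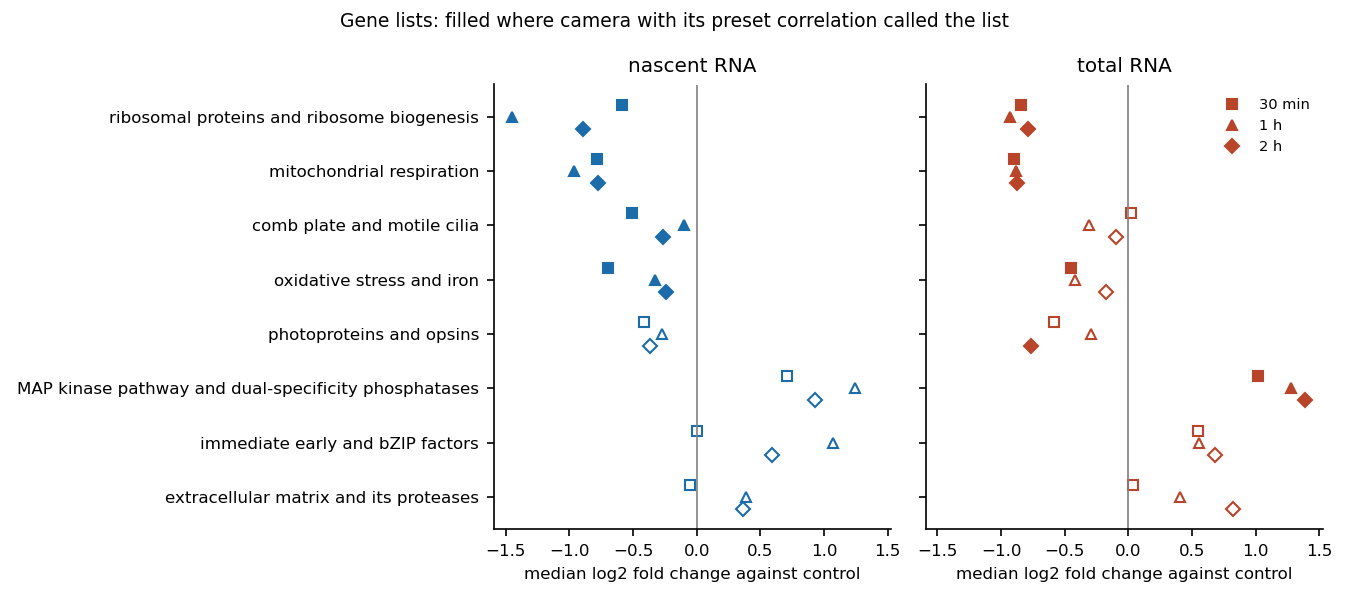
Median log2 change (x axis) of 8 gene lists (y axis) at the 3 times against control in nascent and total RNA, with filled symbols where camera passed at its preset correlation. Ribosomal genes lie at -1.45 in nascent and -0.93 in total RNA at 1 hour, and no list passed with an estimated correlation.

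Between 2 hours and 30 minutes limma called 0 genes in nascent RNA, with 401 at an unadjusted p under 0.05 where chance gives 349, and 0 under both scalings. The genes of smallest p were prolyl 4-hydroxylase alpha-1 (ML257632a, log2 difference 4.29, limma adjusted p = 0.130) and v-Fos (ML182032a, -3.30, limma adjusted p = 0.130), at 2749, 2606 and 2430 RPKM at 30 minutes and 475, 296 and 128 RPKM at 2 hours. Cointegrator subunit 1 (ML293113a, 4.28), a nicotinamidase-like hit (ML090120a, 2.55) and the unnamed ML021127a (3.88) and ML085027a (3.21) followed. The ribosomal list lay below other genes in this difference (camera adjusted p = 0.0220, and adjusted p = 0.945 with an estimated correlation) and the heat shock list above them (0.0238, and adjusted p = 0.580 with an estimated correlation). The first was 0.457 after quantile normalization, 0.291 and 0.214 without 30 minutes replicates 1 and 3, 0.0521 without control 1, and turned upward without 2 hours replicate 2 (0.371). The second was 0.179 with equal medians of ratios, 0.0818 after quantile normalization, and 0.0987, 0.156, 0.317 and 0.0521 without 30 minutes 1 and 2, 2 hours 3 and control 1.

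Calls were shared between times. In total RNA v-Fos and the secretory peptide-37 gene ML200246a were among 1072 genes up at all 3 times, and epi-1 and multivesicular body protein 1b among 462 down. Rises shared by 30 minutes and 1 hour, 30 minutes and 2 hours, and 1 hour and 2 hours numbered 1129, 1208 and 1510, where independent lists would share 351, 369 and 502. Shared falls numbered 543, 505 and 517 against 76.2, 65.1 and 68.3. Heat shock cognate 4 (ML18558a) and dynamin-binding protein (ML149624a), named after their values were seen, rose at 30 minutes and 2 hours (1.77 and 1.74, 0.74 and 0.98) and fell at 1 hour (-1.99 and -1.77). The rises of heat shock cognate 4 did not pass without control replicates 1 and 2, which leaves 1 control library that is assumed to vary like the other groups (limma adjusted p = 0.0840 and 0.0739). In nascent RNA AHNAK and secretory peptide-37 (ML039715a) were among 12 genes up at all 3 times, and transporter-like 11 (ML218834a) among 7 down. The 19 were 10, 8 and 10 without 1 hour 1, 2 and 3, 8, 7 and 55 without 2 hours 1, 2 and 3, 9 and 53 without 30 minutes 1 and 3, and 7 and 32 without control 1 and 3. Shared rises numbered 29, 13 and 21 against 0.421, 0.115 and 0.276 for independent lists, and shared falls 15, 7 and 13 against 0.222, 0.0754 and 0.122. Simulated unchanged groups against the same controls shared 0 calls (100 simulations). Unchanged genes are almost never called after adjustment, so this 0 cannot measure overlap through shared controls. The simulation also drew genes independently, without the lower detection of the controls. The changes correlated across genes, which are not independent replicates, at r of 0.870, 0.934 and 0.903 in total RNA and 0.827, 0.745 and 0.843 in nascent RNA, where simulation gave 0.497 to 0.499. Their covariance was 1.51, 1.65 and 1.67 against a simulated 0.161 in total RNA, and 1.93, 1.51 and 1.77 against 0.533 to 0.534 in nascent RNA. The 3 controls cannot be split into sets of at least 2 libraries, so part of the excess may come from the shared controls.

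The last comparison set the change in nascent RNA beside that in total RNA. V-Fos (ML182032a) and AP-1 (ML1541120a) rose in both at 30 minutes (4.27 and 7.02, 5.80 and 4.79), as did metalloproteinase-24 (4.04 and 3.55) and secretory peptide-37 ML039715a (5.31 and 4.86). AHNAK (ML218819a) rose in nascent and fell in total RNA at 1 hour (7.02 and -1.30, difference 8.33, limma adjusted p = 0.00247). Actin (ML322211a) differed the other way (0.53 and 4.60, difference -4.07, limma adjusted p = 0.0179), as did galactosylceramide sulfotransferase (ML238318a; -1.48 and 5.24, limma adjusted p = 0.00184). Epi-1 (ML120750a) differed at 30 minutes (0.96 and -4.50, limma adjusted p = 0.00518), and protein kinase 3 (ML141214a) at 2 hours (5.79 and 1.66, limma adjusted p = 0.00229). Of 5785 genes tested in both tables, the change differed in 187, 149 and 125 at the 3 times in order. Genes up in both numbered 15, 31 and 10 against 6.02, 19.4 and 5.89 for independent lists (Fisher's exact p = 3.05e-04, 0.00357 and 0.0568, genes not being independent). Genes down in both numbered 9, 11 and 4 against 3.40, 5.97 and 1.70 (Fisher's exact p = 0.00466, 0.0441 and 0.0830), and opposite calls 1, 8 and 3. Changes correlated across genes at r = 0.207, 0.329 and 0.259 (jackknife SE over libraries 0.0435, 0.0664 and 0.0995), with rho = 0.229, 0.348 and 0.270. The median SE of a change was 0.913 in nascent and 0.386 in total RNA. Quantile normalization gave r = 0.146 at 30 minutes and 0.238 at 1 hour, and 279 differing genes at 1 hour. The 187 became 309 and 454 without nascent 2 hours 3 and 30 minutes 3, and 99, 74 and 93 without total 30 minutes 1 and 2 and control 1. The 149 became 77 and 84 without nascent 1 hour 1 and 2, 263, 257 and 255 without nascent 2 hours 3, 30 minutes 3 and control 3, and 66, 74, 53, 85 and 65 without total 1 hour 1, 2 and 3 and control 1 and 2. The 125 became 216 without nascent control 3, and 69 and 70 without total 1 hour 1 and 3, 39, 39 and 52 without total 2 hours 1, 2 and 3, 78 without total 30 minutes 1, and 50 and 78 without total control 1 and 2.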

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

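The test on the 1-read value of the P1 gene was chosen only after its result was seen. A difference between the changes in nascent and total RNA, by limma's test of the difference itself, marked each result below. The single genes were first limited to those named for the largest changes within a table, in these same libraries. Their differences were therefore selected to be large and do not represent all genes whose change differed.

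The change differed in 187 genes at 30 minutes, 149 at 1 hour and 125 at 2 hours. The labels tie nascent RNA to epithelium with comb rows and total RNA to epithelium alone, so kind of RNA, tissue and injury cannot be told apart. Among 100 random splits of the 6 and 6 libraries, 5, 6 and 6 gave as many genes, the real one included, with up to 845, 1493 and 1212. Splits that kept the total RNA groups whole made up 5 of 5, 4 of 6 and 6 of 6 of these. Such splits keep the total RNA change, or its reverse, in the difference, so they cannot test grouping by chance. Of 93 splits that mixed the total RNA groups 0, 2 and 0 gave as many, with up to 98, 179 and 71. These counts alone do not exclude grouping by chance. In simulated data 11.7% of calls of a differing change were false.

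Differences of nascent minus total log2 change, each by limma, were as follows. At 1 hour, the AHNAK hit ML218819a differed by 8.33 (adjusted p = 0.00247), the corepressor CIR1 ML03296a by 7.62 (0.0103), sorbin ML10213a by 7.25 (0.0160), ATRX ML069124a by 5.93 (0.0160), multidrug resistance protein 1A ML06974a by 5.74 (7.40e-04), Rac1 ML274423a by 4.78 (0.0497), MLL3 ML015714a by 4.38 (0.0339), SRSF12 ML31014a by 4.35 (0.0179), mitochondrial L18 ML05739a by 3.44 (0.0448) and H/ACA subunit 1 ML02548a by 2.98 (0.0453). Lower in nascent RNA at 1 hour were galactosylceramide sulfotransferase ML238318a (-6.72, 0.00184), actin ML322211a (-4.07, 0.0179) and obscurin ML19853a (-3.98, 0.0164), which has a near copy. At 2 hours the tetranectin-like ML056964a differed by 8.24 (0.0375), sfc7 ML128437a by 6.02 (0.00220), protein kinase 3 ML141214a by 4.14 (0.00229) and glutamate dehydrogenase ML17724a by -3.30 (0.0142). At 30 minutes the elastin-like ML069131a, with 1 total RNA control also at 0, differed by 7.47 (0.0228), the secreted protein hit ML19406a by -7.43 (0.0197), mitochondrial GTPase 1 ML07975a by -5.89 (0.0146), epi-1 ML120750a by 5.46 (0.00518), prolyl 4-hydroxylase ML257632a by -5.09 (6.02e-04), cointegrator subunit 1 ML293113a by -4.18 (0.0152) and multivesicular body protein 1b ML124217a by 3.87 (0.0284).

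The acidic ribosomal protein P1 hit ML02404a differed by 10.22 at 1 hour (0.0203). In total RNA it was at 777, 93.0 and 394 RPKM in controls, 723, 879 and 322 at 30 minutes, and 401, 286 and 555 at 2 hours, but at 2.64e-28 RPKM or less in all 3 libraries of 1 hour. In nascent RNA it was at 0 in all controls and at 58.2, 0 and 0 RPKM at 1 hour, so the nascent change rests on 1 library. The blastp search found no match to the P1 hit among the proteins of the tables, so no identity was measured. A match too weak for the E-value limit, or a gene that is not listed, would have been missed. Assignment of its reads to a similar gene therefore stays open. The values of 1 hour lie far under the 0.227 RPKM that 1 read is worth, as an estimate set near 0 and not a count would give. Whether the transcript was low remains open.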

How the results depend on the processing

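Tests with a mean of at least 20 RPKM, without the libraries with most genes at 0, with a separate spread in each table and with lists after quantile normalization, without each library or without members of another function were chosen only after the data were seen. No paired analysis was possible because the labels give no replicate numbers shared between groups. Low depth limits genes under a few RPKM. No named gene turned its sign in the settings run. The ribosomal list in nascent RNA at 2 hours against 30 minutes turned upward without 2 hours replicate 2 (camera adjusted p = 0.371). The cause of the moves was not tested. Some settings also used fewer genes or libraries.

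Counts in nascent RNA in time order were 66, 84 up with 50 down, and 40, with 33 at any time and 19 in 1 direction at all times. With a pseudocount of 0.1 the first was 43, and with 5 the third was 62, any time 50 and all times 32. The balance of rises and falls turned with a pseudocount of 5, from 35 and 31, 84 and 50, and 23 and 17 to 27 and 42, 53 and 66, and 21 and 41. Without a filter 2 hours gave 25. Equal medians of ratios gave 74 at 1 hour and 23 at 2 hours, and no trend 47, 26 and 15 (1 hour, 2 hours, any time). Array weights gave 109, 750 and 163, with 194 at any time and 58 at all times. With only the groups compared limma called 0 (856 at an unadjusted p under 0.05), 568 and 1. Without the libraries with most genes at 0 (control 1, 2 hours 3), 1 hour gave 87 and 2 hours 21.

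Counts in total RNA were 1994, 2500 and 2485, with 2220 at any time and 1534 at all times. With a mean of at least 5 RPKM they were 1256, 1430, 1371, 1291 and 945, and of at least 20 RPKM 486, 534, 492, 469 and 349, where fewer genes were tested. Array weights gave 4039 and 3871 at 1 and 2 hours, 3997 at any time and 2496 at all times. With only the groups compared 30 minutes gave 582. Without the libraries with most genes at 0 (control 1 and 2), which leaves 1 control library that is assumed to vary like the other groups, 30 minutes gave 1215 (599 up and 616 down, against 1303 and 691), any time 1253 and all times 935. At 1 and 2 hours rises still led there (1067 and 742, 1108 and 649).

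Genes whose change differed between the tables were 187, 149 and 125. Array weights gave 288, 578 and 280, a mean of at least 20 RPKM 68, 81 and 42, and only the groups compared 48, 291 and 40. A pseudocount of 0.1 gave 77 at 2 hours, quantile normalization 279 at 1 hour, and leaving out the libraries with most genes at 0, with 1 total RNA control left, gave 78 at 2 hours. The correlation of changes was 0.146 at 30 minutes and 0.238 at 1 hour after quantile normalization, against 0.207 and 0.329. Of 184 gene set tests 29 passed, and 0 with an estimated correlation.

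Leaving out each library gave, in nascent RNA, 10 to 348 genes at 30 minutes, 13 to 333 at 1 hour, 11 to 105 at 2 hours, 0 to 0 for 2 hours against 30 minutes (401 at an unadjusted p under 0.05 in limma with all libraries), 6 to 133 at any time and 7 to 55 at all times. In total RNA it gave 1240 to 2368, 1715 to 2773, 1721 to 2806, 0 to 1, 1549 to 2449 and 1030 to 1850. The differences between tables were 74 to 454, 53 to 263 and 39 to 216, the correlations 0.168 to 0.227, 0.271 to 0.364 and 0.199 to 0.322, and the gene set tests 25 to 36. Of the named genes, 2 of 17, 1 of 37 and 3 of 12 calls in nascent RNA and 68 of 90, 86 of 99 and 76 of 95 in total RNA held without each library. In every setting that tested their gene, 0, 1 and 0 of these nascent calls and 46, 66 and 61 of the total RNA calls held. Of the 23 settings, a mean of at least 20 RPKM tested only 53 of the 66 nascent and 110 of the 284 total RNA calls. Of 66 named nascent calls 37 were lost without trend, 31 with only the groups compared, 24 with equal medians of ratios, 21 after quantile normalization, 17 with a pseudocount of 0.1, 15 without a filter and 57 without control replicate 1. Of 284 in total RNA 85 were lost with 1 control library left, which is assumed to vary like the other groups, 55 with only the groups compared and 23 after quantile normalization.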

Other observations

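The Gene Ontology tests, the share of rises among well expressed genes, the rescaled count for the total RNA controls and the transposon pattern itself were chosen only after the data were seen.

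Genes annotated with blood coagulation, the clotting of blood in vertebrates, lay above other genes in total RNA at 30 minutes (17 of 39 up, 2 down; camera adjusted p = 0.00865, and adjusted p = 0.997 with an estimated correlation). At 1 hour and 2 hours 21 were up and 1 down (camera adjusted p = 0.0429 and 0.0188, and adjusted p = 0.997 and 1.00 with an estimated correlation). Genes of fatty acid beta-oxidation, which burns lipids in mitochondria, lay below other genes at 30 minutes and 2 hours (5 and 3 of 12 down; camera adjusted p = 0.0183 and 0.0113, and adjusted p = 0.997 and 1.00 with an estimated correlation) but did not pass at 1 hour (2 down; camera adjusted p = 0.103, and adjusted p = 0.997 with an estimated correlation). Genes annotated with mitotic spindle elongation lay below other genes in total RNA at each time, with 7, 7 and 6 of 12 down (camera adjusted p = 0.00220, 0.00153 and 0.00224, and adjusted p = 0.997, 0.997 and 1.00 with an estimated correlation). They also did so in nascent RNA at 1 hour and 2 hours (camera adjusted p = 8.31e-06 and 0.00757, and adjusted p = 0.753 and 0.999 with an estimated correlation). Overlap of this term with the ribosomal list was not checked.

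Genes annotated with RNA-directed DNA polymerase activity or DNA-mediated transposition (115) had a median log2 change in nascent RNA of 1.47 at 30 minutes, 1.93 at 1 hour and 1.09 at 2 hours. Their median level was 0, 0 and 0.0131 RPKM in the control libraries, 5.18, 5.52 and 0.251 at 30 minutes, 11.5, 2.05 and 3.08 at 1 hour, and 2.64, 3.27 and 0 at 2 hours. Limma called 2, 1 and 0 of them up and 0 down (44, 53 and 13 at an unadjusted p under 0.05). The term for RNA-directed DNA polymerase activity had a camera adjusted p of 1.77e-09, 6.92e-09 and 0.00938 (adjusted p = 0.997, 0.928 and 0.999 with an estimated correlation). At 2 hours against 30 minutes the 115 genes had a median log2 difference of -0.64, against 0.17 for all genes, and limma called 0. The same term lay below other genes there (camera adjusted p = 3.09e-05, and adjusted p = 0.987 with an estimated correlation). In total RNA 11, 26 and 23 of 64 such genes were up and 4, 4 and 3 down.

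For the transposon terms in nascent RNA, without members that have near copies the median at 30 minutes was 1.44 (bootstrap 1.25 to 1.65) against 0.179 for all genes. The median of all members, 1.47, lay at percentile 100 of 10000 random lists of like level, whose median was 0.463 and highest value 1.07, and without control replicate 1 the difference from all genes was 1.57 (1.35 to 1.82). Near copies among the listed genes and control replicate 1 alone thus did not account for the pattern. Copies that are not listed could not be seen, and control replicates 2 and 3 also had median levels of 0 and 0.0131 RPKM. The bootstrap and the random lists took genes as independent, and the term did not pass with an estimated correlation. Low detection in all controls, injury and a difference between libraries therefore stay open.

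In total RNA the controls stood apart from each regenerating time while 2 hours against 30 minutes gave 0 calls (456 at an unadjusted p under 0.05 in limma). Of genes with at least 20 RPKM 41.004% were called at 1 hour, against 37.959% of all, and equal medians of ratios gave 2732 genes against 2500. Calls were thus not confined to genes of low level. A change is easier to call at higher levels, so this share cannot tell how many calls lower depth caused. Of genes with a mean of 1 to under 2 RPKM 26.9% rose and 4.94% fell, against 20.2 and 20.8% at 20 RPKM or more. Equal medians of ratios did not lower the number of calls. Falls went from 726 as deposited to 1072 there, and to 1231 after quantile normalization. Among genes with at least 20 RPKM 49.2% of calls at 1 hour were rises, against 71.0% of all calls. Lower depth of the controls may thus account for part of that excess of rises. At 2 hours a separate fit of only genes with at least 20 RPKM gave 288 up and 204 down. That is another time and another fit, so it cannot be set against the share at 1 hour. Quantile normalization at 2 hours gave 1182 up and 1181 down over all genes tested. A response to injury and a difference in how control tissue was handled both stay open.

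The libraries of 3 against 3 allow only 10 splits, too few to exclude grouping by chance. In nascent RNA 1 of 10 splits gave as many genes at each of the 3 times against control (highest other 5, 0 and 4). In total RNA 1 of 10 did so as well (highest other 1, 4 and 0). For 2 hours against 30 minutes the real count was 0 in both, so 10 of 10 splits gave as many by construction. The highest other count there was 18 in nascent and 2 in total RNA. For any time, 4 of 100 splits gave as many as the 33 genes in nascent RNA, the real one included, with up to 260. Some other groupings of the nascent libraries thus gave more calls than the real one, and why was not tested. In total RNA 1 of 100 splits, the real one, gave as many as the 2220, with up to 1653 in the others.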
